A study of Mus musculus with 11 samples.

How the data were processed

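RNA was measured in the CA1 field of the mouse hippocampus, dissected under a microscope and frozen. There were 6 libraries from CamkdeltaC transgenic mice and 5 from littermate controls, all 3 months old. Both sexes were used, and the labels do not give the sex, litter or batch of a library. Per the labels, polyadenylated RNA was prepared with an unstranded TruSeq kit and sequenced as single-end reads of 50 bases. Nothing in the labels states that each library is a separate animal. If some shared an animal, the p-values would measure only the spread between these samples, which may be technical.

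The authors deposited a raw count per gene for each library, for 48709 Ensembl gene identifiers, made on the mouse build mm10. FastQC 0.11.5, STAR 2.5.2b, featureCounts and Subread 1.5.1 are listed per the submitters' processing notes. The role of each tool and the settings are not given in the sources used here. The authors also deposited a table of 1780 genes higher and a table of 2014 genes lower in transgenic mice. Each gives a log2 fold change computed by the authors and an adjusted p-value computed by the authors. Their per-library values are a signal the authors deposited, in which each count is divided by one size factor per library. The tool behind these tables is not given in the sources used here. All of their adjusted p-values were at most 0.0499.

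Gene names, positions, biotypes, GC content and lengths were taken from the GENCODE mouse annotation on the same build, in which 48349 identifiers had a name and 360 did not. Of the 3794 symbols in the authors' deposited tables, 3750 equalled those of the annotation. GC content was that of the longest annotated transcript and length that of the union of exons. A GC value was available for 17246 of the 17293 genes tested.

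Total counts per library ranged from 14263784 to 36898689. The counting settings were not known, and genes that share sequence with pseudogenes, paralogs or nuclear copies of mitochondrial DNA are uncertain. Because the kit does not mark strand, overlapping and antisense genes cannot be separated either. Pairs of libraries within a group differed by a chi-square per degree of freedom of 6.75 to 53.8, so each was treated as a separate library.

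Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by genotype, which left 17293 genes holding 99.9% of the counts. Libraries were scaled with TMM. The quasi-likelihood F test compared transgenic with control in all 11 libraries without a covariate, and Benjamini-Hochberg adjusted p under 0.05 called a gene. Standard errors were derived from the fold change and the F statistic. Log2 CPM values used a prior count of 2. The 38 gene lists were fixed before the data were examined, as were the design, the alternatives and the rule for named genes, except where stated below. The 37 lists with at least 5 measured members were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, and again with an estimated correlation and with fry. Camk2d was tested with a two-sided exact permutation of mean log2 CPM over the 462 splits of the libraries into 6 and 5.

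Named genes followed a rule. They were Camk2d and its relatives, and the 8 called genes with the largest rise and the 8 with the largest fall that had a mean log2 CPM of at least 1, a gene symbol that was not a Gm number, a Rik name, a pseudogene name or a clone name beginning with AC, AI or BC, and the same direction in every fit with 1 library left out. To these were added up to 3 members with the smallest p from each list that was called or held at least 3 called members. This gave 71 genes, some of which are omitted for brevity and 4 of which are not reported here.

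The alternatives were the size factors of DESeq2, upper-quartile scaling, no filter, a filter of CPM above 1 in at least 5 libraries, DESeq2 1.42.0, limma voom with sample weights, the replicate number as a block, the level of Xist as a covariate, 1 surrogate variable from sva 3.50.0, removal of a length trend, and leaving out each library in turn. Removal of a GC trend, alone or together with a length trend, was added after seeing the data. For each library a lowess curve with a span of 0.3 of the deviation of log2 CPM from the gene's mean was fitted on GC content and entered as an offset. List scores, also added after seeing the data, were the mean of that deviation over the members of a list, for all 38 lists. They were compared by two-sided exact permutation over the 462 splits. Calls were also counted in 60 of these splits, the real one included. For 10000 random lists, each member was replaced by 1 of the 50 protein-coding genes nearest to it in GC content, length and expression. A further list of 12 measured long noncoding RNAs known to stay in the nucleus was written before its values were seen, though after the other results.

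The procedure was tested on simulated counts for the 17293 genes, with 200 changed genes. It recovered 80% of changes of 0.5 and 98% of changes of 1 on the log2 scale, with 8 false calls. When the observed GC trends were added to the simulated libraries, the fit without correction made 719 false calls and the fit with the GC trend removed made 5. The simulated dispersions were estimated from the real libraries with their GC trends still present. The spread therefore held the trends already, and these counts need not match those of the real libraries.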

Results

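Gene expression was profiled in hippocampal CA1 at 3 months of age, in 6 libraries from transgenic mice and 5 from littermate controls. CamkdeltaC is a splice form of the delta subunit of calcium/calmodulin-dependent protein kinase II, and the transgenic line is a model of heart failure in which the transgene is driven by a heart promoter. The series title links heart failure to memory impairment, and the comparison asks which transcripts differ in a brain region needed for memory. Transgenic libraries held 24403918 to 34153726 counts. Control 5 held 14263784 counts and the other controls 31679533 to 36898689. Genes on the mitochondrial chromosome took 3.01% to 5.04% of the counts.

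Camk2d, the gene carried by the transgene (ENSMUSG00000053819, chromosome 3, 126596302 to 126846326, build mm10), did not pass the test between the groups in CA1. Its level was 67.8 ± 36.7 CPM in transgenic libraries (SD, n = 6) and 72.0 ± 18.6 CPM in controls (SD, n = 5). The mean log2 CPM differed by -0.20, with an exact two-sided permutation p of 0.567. The edgeR estimate was -0.08 with a standard error of 0.29 and an adjusted p of 0.873. Neither test adjusts for sex, which the labels do not give per library. Camk2d was at 89.8 to 132 CPM in the libraries with high counts of the Y-linked Ddx3y (transgenic 4 and 6, control 2 and 5) and at 40.4 to 61.6 CPM in the others. Where Xist was high, transgenic 1 to 3 stood at 40.4 to 47.3 CPM and control 1, 3 and 4 at 53.7 to 61.6 CPM. Where Ddx3y was high, the groups overlapped. These subsets were not tested, and the missed threshold does not show equal levels. With the level of Xist as a covariate the edgeR estimate was -0.27 (adjusted p 0.290), and with 1 surrogate variable Camk2d passed the threshold at -0.33 (adjusted p 0.0421). Leaving out transgenic 6 moved the difference in mean log2 CPM to -0.42 (exact permutation p 0.159). The differences were -0.32 and -0.13 without transgenic 4 and 3, -0.09 and -0.08 without transgenic 1 and 2, and -0.09 and -0.11 without control 2 and 5. Transgenic 6 had the highest level, 132 CPM, and transgenic 2 the lowest, 40.4 CPM. The brain-enriched relatives Camk2a and Camk2b, which form the main kinase of excitatory synapses, had log2 fold changes of 0.14 and 0.19 and adjusted p of 0.340 and 0.127. Camk2g had 0.16 and 0.288. Camk2b passed the threshold without transgenic 6 (0.24, adjusted p 0.0195) and with limma voom and sample weights (0.23, adjusted p 0.0338). It also passed with the replicate number as a block (0.24, adjusted p 0.0286), a fit to whose contrast transgenic 6 adds nothing. Camk2a passed with 1 surrogate variable (0.17, adjusted p 0.0440). Since the line expresses its transgene in the heart, these levels do not test the labels.

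**Figure D1:**
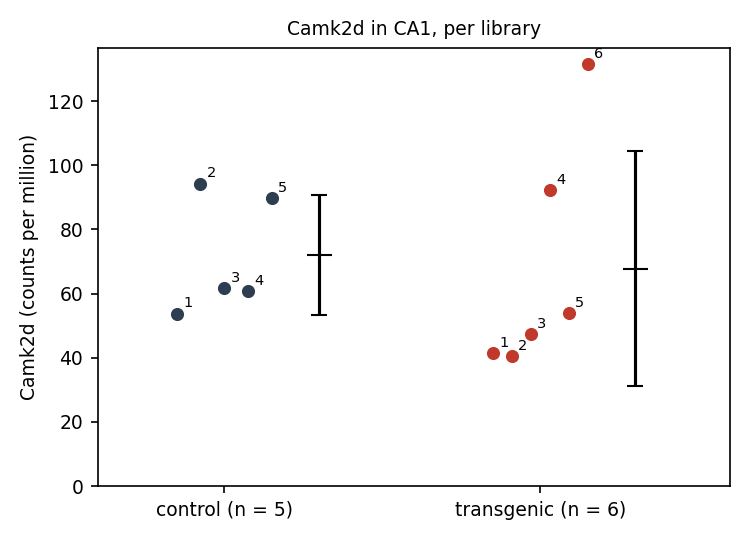
Camk2d in CPM, its share of the library's counts scaled to a common total (vertical axis), for each control and transgenic library, numbered by replicate, with the mean and SD beside each group. The groups overlap, and the highest library, transgenic 6, stands at 132 CPM. Transgenic 4 and 6 and control 2 and 5, the libraries with high Ddx3y, stand above all others.

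In transgenic CA1, 3094 of 17293 tested genes changed at an edgeR adjusted p under 0.05, of which 1282 rose and 1812 fell. Among genes that met the naming rule, the largest rises were Mir6236, an annotated microRNA gene, by 2.24 on the log2 scale (SE 0.40), and CT010467.1, annotated as ribosomal RNA, by 2.01 (SE 0.40). Lars2, the mitochondrial leucyl-tRNA synthetase, rose by 1.32 (SE 0.27), from 53.9 ± 8.11 CPM in controls (SD, n = 5) to 135 ± 60.2 CPM (SD, n = 6). Efcab6 rose by 0.84 (SE 0.18). Gkn3, Atoh8, a transcription factor, and Scand1 rose by 0.74, 0.67 and 0.63.

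Under the same rule, the largest falls were in Gbp4, an interferon-induced GTPase, at -1.46 (SE 0.44), and Ikzf5, a zinc finger factor, at -1.35 (SE 0.35). Zfp738 and Zxdb, further zinc finger genes, had -1.30 and -1.09. Gt(ROSA)26Sor, a noncoding gene, and Sycp1, a meiotic chromosome protein, had -1.07 and -0.98. Prrg1 and Lypla1, a depalmitoylating enzyme, had -0.98 and -0.96. These falling genes were sparsely expressed, from 3.43 ± 0.932 CPM in controls for Ikzf5 to 21.7 ± 3.58 CPM for Lypla1 (SD, n = 5). Ikzf5 overlaps Fgfr2 and Pstk, Gbp4 overlaps Gbp8 and Gbp9, and Gt(ROSA)26Sor overlaps Thumpd3, so their reads cannot be told from those of these neighbours. Zfp738 was called in 2 and Gbp4 in 3 of the 11 fits that each left out 1 library. These falling genes all missed the threshold once the GC trend was removed (adjusted p of 0.0753 to 0.275), and so did Gkn3, Atoh8 and Scand1 among the rising genes. Several folds stayed about as large, with Zxdb at -1.12 (SE 0.31), Gbp4 at -1.27 (SE 0.45), Ikzf5 at -1.06 (SE 0.30) and Gkn3 at 0.69 (SE 0.20), while Prrg1 and Sycp1 went to -0.36 (SE 0.14) and -0.41 (SE 0.18). Since fewer genes have a small p-value after the removal, the Benjamini-Hochberg adjustment is stricter there, and a gene can lose its call at a similar fold.

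Across genes, the fold change followed the GC content of the transcript. The median GC content was 56.1% in genes that rose, 41.6% in genes that fell and 49.6% in all genes. The rank correlation of log2 fold change with GC content was 0.684 across genes, which are not independent replicates. Within each library the slope of log2 CPM deviation per 10 GC points was 0.127 ± 0.134 in transgenic libraries (SD, n = 6) and -0.153 ± 0.0640 in controls (SD, n = 5), with an exact permutation p of 0.00433. The slopes of transgenic 1 to 6 were 0.274, 0.259, 0.176, 0.099, 0.016 and -0.061. Those of control 1 to 5 were -0.119, -0.062, -0.201, -0.220 and -0.161. When each library's GC trend was removed, 342 genes changed, of which 200 rose and 142 fell. Of them, 228 were among the 3094 in the same direction. The share that rose moved from 41.4% to 58.5%. Genes called after the removal had a median GC content of 43.7% if they rose and 43.8% if they fell, below that of all genes. Some were called only after it, such as Vdac3, at 0.07 before (adjusted p 0.432) and 0.47 after (adjusted p 0.0314). The call count without correction also depended on single libraries. It was 4712 without transgenic 6, 1155 without control 4, 1285 without transgenic 2, 1289 without control 5, 1480 without transgenic 3, 1572 without control 3, 1670 without transgenic 1 and 1835 without control 1.

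**Figure D2:**
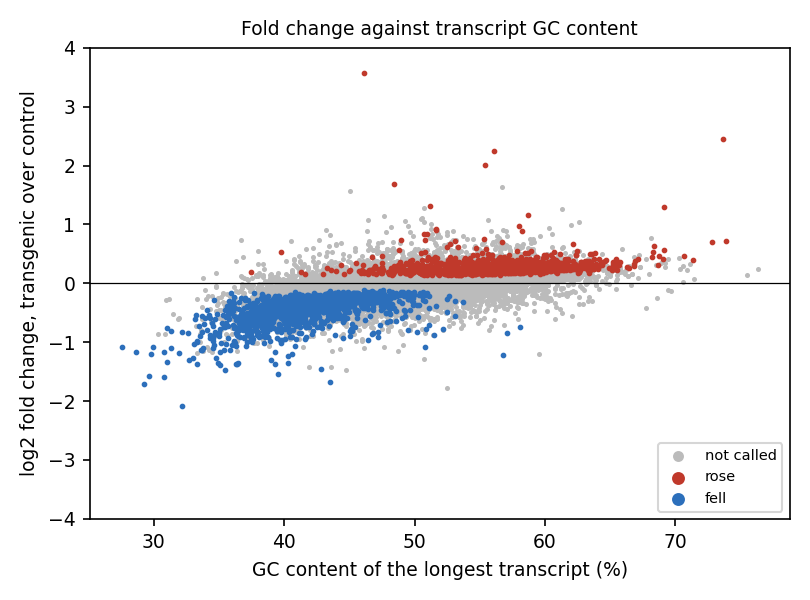
Log2 fold change, transgenic over control (vertical axis), against the GC content of the longest transcript in percent (horizontal axis), one point per tested gene with a GC value. Genes that rose have a median GC content of 56.1% and genes that fell 41.6%.

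**Figure D3:**
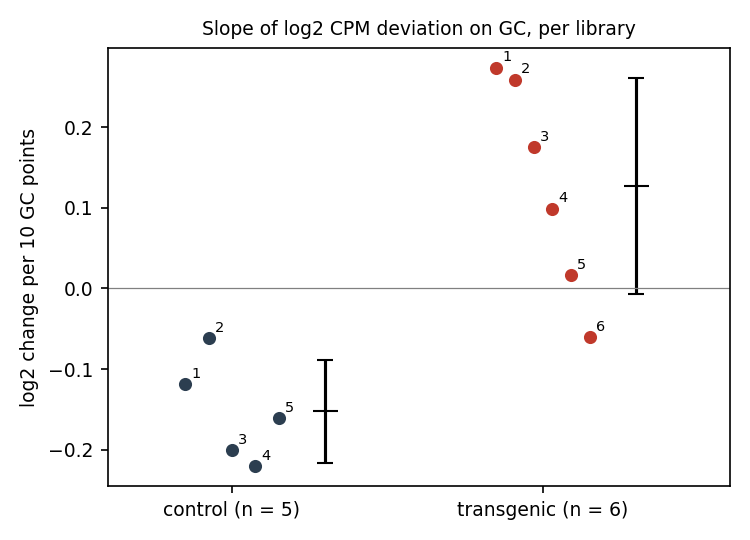
Slope of log2 CPM deviation per 10 GC points (vertical axis) for each library, numbered by replicate, with the mean and SD of each group. Transgenic libraries lie between -0.061 and 0.274 and controls between -0.220 and -0.062.

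Transcripts of the nuclear-encoded respiratory chain, whose proteins carry out oxidative phosphorylation, rose together in transgenic CA1. Of 71 measured members, 41 rose and 1 fell (46 and 1 adjusted over the list alone). The median log2 fold change was 0.213. The complex I subunits Ndufs7, Ndufa7 and Ndufa6 rose by 0.36 (SE 0.06), 0.33 (SE 0.06) and 0.26 (SE 0.05). Camera gave an adjusted p of 6.6e-17 with the preset correlation, and fry gave 0.0207, but the adjusted p was 0.939 with an estimated correlation. After removal of the GC trend 23 members rose, none fell and the median was 0.149. The mean list score was 0.0864 ± 0.0484 in transgenic libraries (SD, n = 6) and -0.104 ± 0.0697 in controls (SD, n = 5). It was higher in each of the 6 transgenic libraries than in any control, with an exact permutation p of 0.00216, the smallest the design can give, and 0.0411 adjusted over the 38 lists. With GC and length trends removed the scores differed by 0.154 with the same exact permutation p, but 0.0823 adjusted over the 38 lists.

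**Figure D4:**
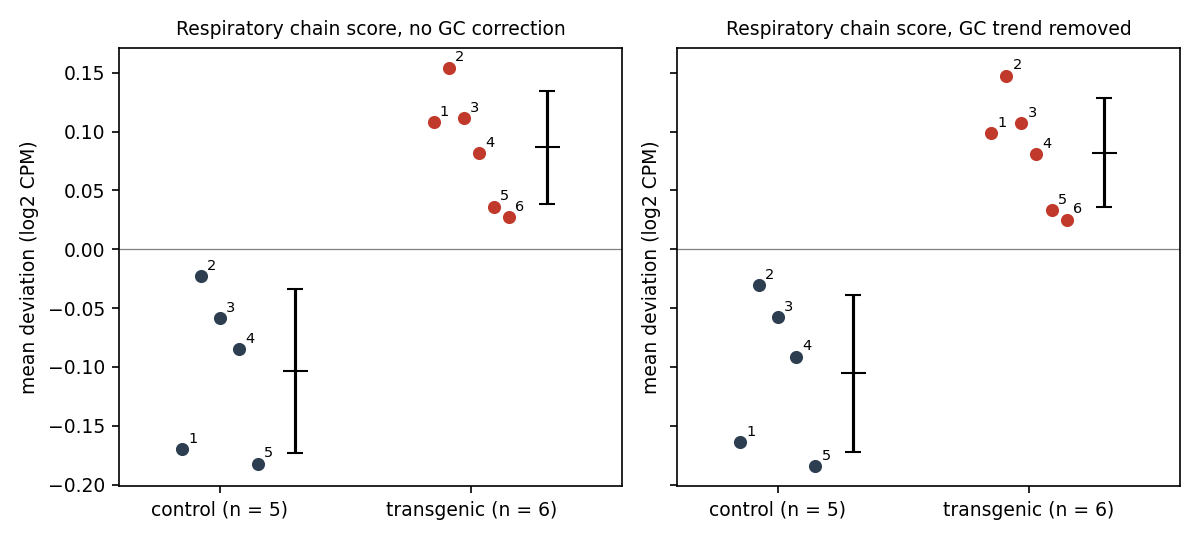
Respiratory chain score, the mean deviation in log2 CPM over 71 genes (vertical axis), per library numbered by replicate, without correction and with the GC trend removed, with the mean and SD of each group. All 6 transgenic libraries lie above all 5 controls in both panels.

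Cytosolic ribosomal protein genes, the protein components of the ribosome, rose as a group. Of 76 measured, 29 rose and 2 fell (35 and 3 adjusted over the list alone). Rps21, Rps14 and Rpl8 rose by 0.40 (SE 0.07), 0.38 (SE 0.06) and 0.32 (SE 0.06). These genes have many pseudogenes, and Rps14 overlaps Ndst1. Proteasome genes, which encode the main protein-degrading complex, rose too, 12 of 31 with none falling (15 adjusted over the list alone). Psmb6, Psmb4 and Psmd4 rose by 0.27, 0.22 and 0.21. The camera adjusted p was 1.06e-07 for the ribosomal and 0.000319 for the proteasome list, 0.939 for both with an estimated correlation. The fry adjusted p was 0.0375 and 0.0641. After removal of the GC trend 8 ribosomal and 4 proteasome genes rose and none fell, at medians of 0.143 and 0.115 against 0.188 and 0.125 before. Rps21 and Rps14 kept their call. Rpl8 (0.14, adjusted p 0.0964), Psmb6 (0.19, 0.0710), Psmb4 (0.14, 0.0859) and Psmd4 (0.11, 0.112) lost it. For the ribosomal and proteasome lists camera then gave adjusted p of 3.02e-10 and 2.78e-12. With an estimated correlation the adjusted p was 0.494 for both, and with fry it was 0.0448 for both.

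Splicing factor genes and voltage-gated ion channel genes were lower. Of 30 splicing factor genes, 18 fell and 1 rose (19 and 3 adjusted over the list alone). Ptbp2, a neuronal splicing repressor, fell by 0.53 (SE 0.10) and Srsf11 by 0.39 (SE 0.06). After removal of the GC trend 1 splicing factor gene rose and 1 fell. The list median moved from -0.27 to -0.06, and Ptbp2 was then at 0.12. Of 35 channel genes, 11 fell and 1 rose (15 and 2 adjusted over the list alone). Cacna2d1, a calcium channel subunit, fell by 0.58 (SE 0.09). Scn3a, a sodium channel, fell by 0.53 (SE 0.08). Removal of the GC trend left 4 channel genes that fell and a median of -0.12, against -0.18 before. The channel score differed between the groups by -0.16 before and -0.14 after that removal, with an exact permutation p of 0.00216 both times and 0.0411 adjusted over the 38 lists. With GC and length trends removed it differed by -0.098, with an exact permutation p of 0.00649 and 0.0823 adjusted over the 38 lists. Without correction camera gave adjusted p of 8.89e-05 for splicing and 0.00278 for channels, 0.939 for both with an estimated correlation, and fry gave 0.0375 and 0.0456. Removal of the length trend ended the call of the channel list, with an adjusted p of 0.382.

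Microglia markers rose, with 5 of 15 members called and none lower (6 adjusted over the list alone). Trem2, Tyrobp and Csf1r, a receptor, its signalling adaptor and a survival receptor of microglia, rose by 0.45, 0.34 and 0.25. The camera adjusted p was 0.0352, against 0.939 with an estimated correlation and 0.210 with fry. The call was lost without transgenic 5, control 1, control 2 or control 5, at adjusted p of 0.0636 to 0.0900. Camera still called the microglia list after removal of the GC trend (median 0.114, adjusted p 0.00255), with an adjusted p of 0.747 with an estimated correlation. No single marker was then called, Trem2 being at 0.39 with an adjusted p of 0.0512. Of the 7 measured mitochondrially encoded genes 3 fell, mt-Nd2 by 0.50, mt-Nd6 by 0.46 and mt-Nd5 by 0.41, with a list median of -0.41 and a camera adjusted p of 0.00604. The adjusted p was 0.939 with an estimated correlation and 0.144 with fry. Once the GC trend was removed this list turned to a median of 0.186 with a camera adjusted p of 0.00282 and no called member. The adjusted p of this turned list was 0.600 with an estimated correlation and 0.172 with fry. mt-Nd5 overlaps mt-Nd6.

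The number of lists called is no larger than other groupings of the same libraries give. Of 60 splits into 6 and 5 libraries, the real one included, 51 called at least 7 lists with camera and the preset correlation.

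**Figure D5:**
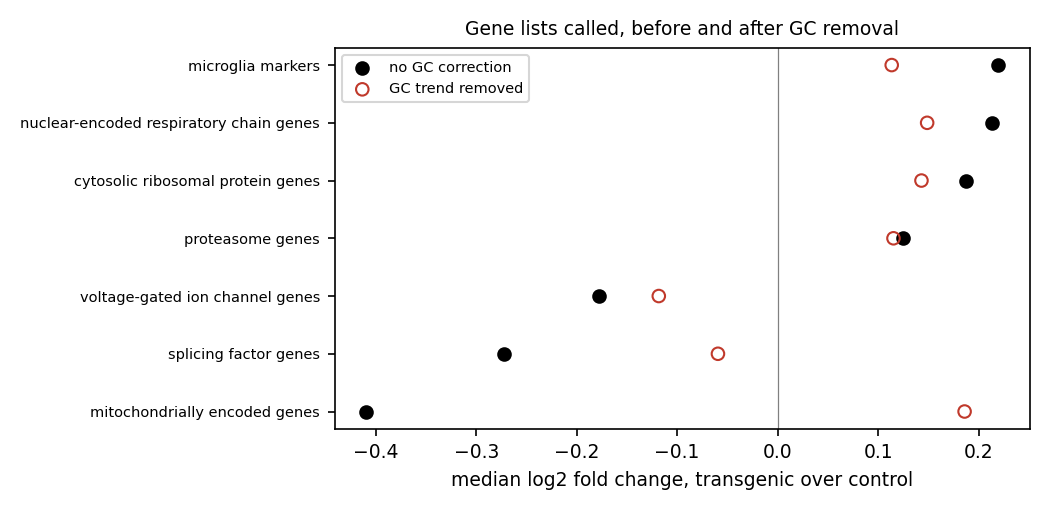
Median log2 fold change, transgenic over control (horizontal axis), of the 7 lists called by camera, without correction (filled) and with the GC trend removed (open). The respiratory chain list stands at 0.213 and 0.149, and the mitochondrially encoded list turns from -0.41 to 0.186.

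The other 30 lists did not pass with camera, the lowest adjusted p being 0.0698 for postsynaptic glutamate receptor and scaffold genes. Of those 30 genes 10 fell. Grm5, a metabotropic glutamate receptor, fell by 0.55 (SE 0.09), Gria2, a subunit of AMPA receptors, by 0.50 (SE 0.08) and Nlgn1, a synaptic adhesion protein, by 0.36 (SE 0.06). With the GC trend removed Grm5 still fell, by 0.33 (adjusted p 0.0314), whereas Gria2 was at 0.02 and Nlgn1 at 0.04. In all, 2 postsynaptic genes were then called. Among 25 presynaptic genes 6 fell and 3 rose. Pclo, an active zone scaffold, fell by 0.34, while Stx1a, a membrane fusion protein, rose by 0.27. Among 30 memory and plasticity regulators 5 fell and 3 rose. Fmr1, the RNA-binding protein lost in fragile X syndrome, fell by 0.77 (SE 0.16) and by 0.41 with the GC trend removed. Braf and Mef2a fell by 0.33 each. After removal of the GC trend no presynaptic gene and 1 memory regulator, Fmr1, was called. The memory list, at a median of -0.033, then passed with fry (adjusted p 0.0448) but not with camera (adjusted p 0.163).

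Chromatin genes went both ways. Among 21 genes of the H3K4 methyltransferase complexes, which mark active promoters and enhancers, 2 rose and 3 fell. Men1 and Cxxc1 rose by 0.25 and 0.22, and Kmt2c, a methyltransferase, fell by 0.28. The camera adjusted p was 0.928. Of 6 H3K4 demethylase genes 1 fell (0.382), though the list passed with fry at an adjusted p of 0.0469, and at 0.241 with the GC trend removed it did not. Of 22 histone acetyltransferase and deacetylase genes 4 rose and 1 fell (0.597), with Hdac5, Sirt2 and Hdac11 rising by 0.25, 0.25 and 0.22. After removal of the GC trend Hdac5, Sirt2 and Hdac11 were at 0.05, 0.13 and 0.05 and none was called. Kmt2c missed the threshold at -0.24 (SE 0.07, adjusted p 0.0710), while Men1 and Cxxc1 were at 0.08 and 0.03. In all, 1 methyltransferase complex gene rose and 1 acetyltransferase or deacetylase gene fell after that removal.

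Without correction, stress programs did not pass as lists. Of 26 genes of the ER stress response 7 fell and 1 rose. Dnajb9 and Canx, chaperones of the endoplasmic reticulum, fell by 0.50 and 0.30, and Atf4, a stress transcription factor, rose by 0.22. Of 18 heat shock genes 4 fell, among them Chordc1 at -0.56, Hspa4l at -0.41 and Dnaja1 at -0.34. Of 17 oxidative stress genes 5 rose and 1 fell, with Mt1, a metallothionein, and Gpx1, a peroxidase, up by 0.39 and 0.31 and Gclm, of glutathione synthesis, at -0.40. The camera adjusted p was 0.312 for each of these 3 lists. No ER stress or heat shock gene was called after removal of the GC trend, and 3 oxidative stress genes rose. Camera then called the oxidative stress list upward (adjusted p 0.0395, 0.747 with an estimated correlation). With GC and length trends removed it called the ER stress list downward (adjusted p 0.0243). The values in brackets that follow are camera adjusted p without correction. Hypoxia genes had 1 rise and 1 fall among 16 (0.405), and none of 15 glucocorticoid response genes was called (0.420). Immediate early genes had 1 fall among 18 (0.312).

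Without correction, cell type markers other than those of microglia did not pass as lists. Among 15 astrocyte markers 3 rose and 1 fell (adjusted p 0.395), the rises being Acsbg1 by 0.26, Aldh1l1 by 0.24 and Mlc1 by 0.23. Among 14 interneuron markers 2 rose and 1 fell (0.420), with Cck, a neuropeptide, and Slc32a1, the vesicular GABA transporter, up by 0.32 and 0.22 and Cnr1, the cannabinoid receptor, at -0.40. No marker in either list was called after removal of the GC trend. One call each came from markers of CA1 pyramidal neurons (0.874), CA3 and CA2 pyramidal neurons (0.312), oligodendrocyte precursors (0.420), endothelium (0.704) and mural cells (0.844), and from heart muscle genes (0.900) and interferon response genes (0.494). No member was called among markers of dentate granule neurons (0.398), cortical and subicular neurons (0.874), thalamic neurons (0.900), choroid plexus (0.509), oligodendrocytes (0.312) and meningeal fibroblasts (0.823). The same was true of calcium/calmodulin kinase genes (0.312), reactive astrocyte and inflammation genes (0.874) and dynein and cilium genes (0.312). Of the red blood cell genes 4 were measured, too few for a test.

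All 3794 genes in the authors' deposited tables had the same direction here, and 2856 of them were called, 1243 higher and 1613 lower. A further 238 genes were called here and not listed. Pearson's r of the log2 fold changes was 0.9996 across the listed genes, which are not independent replicates. The tables come from the same libraries, so this is not independent evidence. In the authors' deposited table Scn3a stood at -0.53 and Gria2 at -0.50. The listed higher genes had a median GC content of 56.1% and the lower genes 42.1%. GC content alone ranked a higher gene above a lower one in a share of 0.991 of pairs. With the GC trend removed 222 of the listed genes were called in the same direction, and 3415 kept their sign.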

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

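The tests of GC content, sex, length, depth, neurons, matched lists and Lars2 were chosen only after the results were seen, whereas those of other splits and of nuclear RNA were set before their values were seen. Of 224 groups of values examined for a library far from the rest of its group, 13 had one, where chance gives about 1 in 20 groups, or 11.2. Control 5 had 14263784 counts, against 31679533 to 36898689 in the other controls. Zfp738 was at a log2 CPM of -2.27 in transgenic 3 against 2.10 to 2.61 in the other transgenic libraries. Mlc1 was at 7.94 in transgenic 2, Cck at 7.91 in transgenic 6, Rps21 at 6.79 and Rpl8 at 7.92 in control 2, and Gkn3 at 1.59 in control 3. The score of CA3 and CA2 neuron markers was 0.638 in control 3 and 0.295 in transgenic 6. Mural cell markers scored 0.320 in transgenic 1. In transgenic 4, calcium/calmodulin kinase genes scored 0.142, immediate early genes -0.687 and ER stress genes -0.133.

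Fold changes in transgenic CA1 followed GC content, and removing each library's GC trend took the called genes from 3094 to 342. A GC trend of each library is thus a candidate source of many calls. Added to simulated libraries, the observed trends gave 719 false calls. The simulated spread held the trends already, so that count need not match the real libraries. The share of the 3094 calls that the trends account for is thus not settled. Of 60 splits of the libraries, the real one included, 2 gave 3094 or more called genes. The highest other, 4642, set transgenic 6 with the 5 controls. With the trend removed 2 of 60 gave 342 or more, the highest other being 866 from that same split. Few of the drawn splits gave as many genes, but chance is not excluded, since the split of transgenic 6 with the controls gave more than the real one. That split is the genotype with 1 library moved, and it points to a structure of the samples in which transgenic 6 lies near the controls. Without correction, transgenic 5 set with the 5 controls, again 1 library moved, gave 2150 called genes. The next highest drawn split gave 91. Gene length is argued against as the source of the link with GC content, since the rank correlation stayed at 0.638 once the length trend was removed. That removal left 2186 called genes, 1862 of them among the 3094 in the same direction. A part played by length in the number of calls thus stays open. A change in neurons alone is argued against too, since the slope in glial and vascular markers was 0.219 (95% interval 0.164 to 0.273). That interval treats the 81 markers as independent replicates, which they are not. Thinning to the smallest total left a slope difference of 0.279. Because thinning keeps each library's relative counts on average, it cannot decide on library depth, which stays open. Handling of the groups in different batches and an effect of genotype on GC-rich transcripts cannot be told apart, because no batch is given and the slopes spread over 0.335 among the transgenic libraries alone. With the level of Xist as a covariate 3072 of the 3094 genes kept their call. That fit cannot decide on sex, since high Xist stood at 594 to 631 CPM in transgenic 1 to 3 and at 1019 to 1088 CPM in control 1, 3 and 4. It also sets transgenic 5, with little Xist and no Ddx3y, with the libraries that have Ddx3y. Both groups hold libraries with high Xist and libraries with Ddx3y, so sex does not separate the groups. A part played by sex stays open, and so does the transgenic genotype.

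Respiratory chain transcripts were higher, with proteasome and ribosomal ones, while channel transcripts were lower, but the number of lists called does not exceed chance, since 51 of 60 splits gave 7 or more (highest other 20), and 34 of 60 gave 11 or more with the GC trend removed (highest other 22). A GC trend of each library is argued against as the whole cause for the respiratory chain list, whose score differed by 0.188 after its removal and 0.190 before, and for the channel list, whose score differed by -0.14 and -0.16, each with an exact permutation p of 0.00216. Shared GC content, length and expression are argued against as the whole cause where a median lay beyond all 10000 matched random lists and removal of the length trend kept the call. This held for the respiratory chain (0.213, highest random 0.181) and ribosomal lists (0.188, highest 0.181). The random lists had medians of 0.115 and 0.105 there, so these traits can account for a part of each rise. Random members were drawn singly, without the correlation within a list. As the whole cause these traits stay open for the channel list (-0.18, lowest -0.16), which went to -0.0407 (adjusted p 0.382) without the length trend and to -0.0927 (adjusted p 0.000127) without GC and length trends. They also stay open for the proteasome (0.125, highest 0.160, percentile 99.4) and splicing lists (-0.27, lowest -0.30, percentile 0.07). A lower share of nuclear RNA stays open, since 12 nuclear-retained long RNAs differed by a score of -0.12 (exact permutation p 0.0541) before and -0.00736 (0.892) after GC removal, and so does the genotype.

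Mir6236, CT010467.1 and Lars2 were higher together, but unevenly among the transgenic libraries. CT010467.1 was at 597, 838, 389, 408, 175 and 117 CPM in transgenic 1 to 6, against 86.2 to 116 CPM in controls. Lars2 was at 60.1 CPM in transgenic 6, below the 65.2 CPM of control 4. Ribosomal RNA reads counted at Lars2 are a candidate explanation, since the deviations of Lars2 and CT010467.1 from their group means had Pearson's r of 0.970 (permutation p 0.00027) and Spearman's rho of 0.936 (permutation p 0.00082) over 11 libraries, the only such relation computed, and r of 0.898 without the 2 libraries farthest from the median. A rise of the mitochondrial synthetases as a class is argued against, because the highest of the 16 other such genes was at 0.31 and their median at 0.03. Whether more ribosomal RNA in transgenic libraries comes from the tissue or from poly(A) selection was not tested.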

How the results depend on the processing

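The GC and GC with length corrections were chosen after seeing the data, and the other alternatives before the data were examined. With the GC trend removed, 342 genes changed (200 rose, 142 fell), 11 lists were called and 222 genes of the authors' deposited tables were called. With GC and length trends removed these were 294 (200 rose, 94 fell) and 150 of the authors' genes. Limma voom with sample weights gave 4774 calls (2164 rose). The number that rose was 662 without a filter and 1973 with 1 surrogate variable. Leaving out each library gave 1155 to 4712 calls, 361 to 2132 that rose and 794 to 2580 that fell. The counts of called list members depended on single libraries too. Of 30 such counts, 15 moved without control 4 and 15 without transgenic 2, against 4 without transgenic 5. In the fit with the replicate number as a block, transgenic 6 has no control of its number and adds nothing to the contrast. That fit is thus close to the one without transgenic 6, which gave 4712 calls. The block fit gave 4594 calls, of which 2053 rose, and Camk2b passed at 0.24. The data gave no sign that the numbers pair the samples. Of 5 same-numbered pairs 1 had a correlation over 0.1, and 1 of 5 samples matched its own number best. So few pairs cannot exclude that the numbers mark a litter or a batch. The cause was not tested for any of these shifts, beyond the test of GC content.

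With an estimated correlation 0 lists were called. The medians were unaltered there by construction, with microglia at 0.219, respiratory chain at 0.213, mitochondrially encoded at -0.41, ribosomal at 0.188, proteasome at 0.125, channels at -0.18 and splicing at -0.27, each at an adjusted p of 0.939. Fry ended the call for microglia (0.219, adjusted p 0.210), mitochondrially encoded genes (-0.41, 0.144) and proteasome genes (0.125, 0.0641). The microglia list also lost its call with CPM above 1 (0.218) and with the length trend removed (0.157), where channels went to -0.0407. Without single libraries the microglia median ranged from 0.155 to 0.260. The call was lost without transgenic 5, control 1, control 2 or control 5. The mitochondrially encoded list turned to 0.186 with the GC trend removed and 0.144 with GC and length removed.

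Of the named genes other than Camk2d and the 4 not reported, 63 were called and 3 were not. With the GC trend removed 14 of the 63 kept their call, 42 lost it in the same direction, the 3 stayed uncalled and 7 lost it and turned: Chordc1 0.0127, mt-Nd5 0.0848, mt-Nd2 0.0530, mt-Nd6 0.186, Gria2 0.0223, Nlgn1 0.0386 and Ptbp2 0.116. With GC and length removed 8 turned: Chordc1 0.0309, Slc32a1 -0.0181, mt-Nd5 0.0482, mt-Nd2 0.00255, mt-Nd6 0.144, Gria2 0.101, Nlgn1 0.101 and Ptbp2 0.146. The Camk2d difference in mean log2 CPM turned from -0.20 to 0.0737 there, not called in either. Its edgeR estimate, -0.08, turned to 0.140 with the length trend removed, 0.0543 with the GC trend removed and 0.167 with both removed. It ranged from -0.384 to 0.0424 over the fits that left out 1 library, and passed the threshold only with 1 surrogate variable, at -0.33. Thinning every library to the 14263784 counts of control 5 left 2628 calls.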

Other observations

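The first 2 paragraphs describe groups and genes chosen after their values were seen. With the GC trend removed, 11 lists were called by camera with the preset correlation, 34 of 60 splits giving as many. They included presynaptic vesicle release genes at a median of -0.08 (adjusted p 0.00626), postsynaptic genes at -0.03 (0.0424), oligodendrocyte and myelin markers at 0.223 (0.0216) and oxidative stress genes at 0.082 (0.0395). The lowest adjusted p over all lists was 0.494 with an estimated correlation. Among the single genes with the smallest adjusted p after removal, Penk, the enkephalin precursor, stood at 0.35, Sf3b5, a splicing factor, at 0.46, and Map2, a dendritic microtubule protein, at -0.36. Pcdh17, a protocadherin, stood at -0.42 and Bmpr2, a BMP receptor, at -0.37.

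Mitochondrial ribosomal protein genes had 21 rises and 1 fall among 77 measured, and 9 rises and 0 falls with the GC trend removed. Genes on the X chromosome had 16 rises and 126 falls among 580, and 9 and 11 after removal. Zfp-named zinc finger genes had 15 rises and 80 falls among 370, and 2 and 0 after removal. Unconfirmed transcripts in the annotation had 0 rises and 93 falls among 441, and 0 and 2 after removal.

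Counts of Xist, the X-inactivation RNA, and of the Y-linked Ddx3y differed between libraries. Xist had 16443, 16409 and 14539 counts in transgenic 1, 2 and 3, and 34217, 37589 and 34474 in control 1, 3 and 4. Ddx3y had 1098 and 2192 counts in transgenic 4 and 6, and 2118 and 1078 in control 2 and 5. Transgenic 5 had 22 counts of Xist and 0 of Ddx3y among 30185091, which allows up to 3 counts of Ddx3y. Camk2d was at 92.2 and 132 CPM in transgenic 4 and 6 and at 94.3 and 89.8 CPM in control 2 and 5. It was at 41.4, 40.4, 47.3 and 54.0 CPM in transgenic 1, 2, 3 and 5, and at 53.7, 61.6 and 60.7 CPM in control 1, 3 and 4.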
